A study of Mus musculus with 11 samples.

How the data were processed

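RNA was measured by sequencing in EGFP+ mononuclear phagocytes sorted from the epididymis of CX3CR1 EGFP +/- mice aged 12 weeks, in which EGFP marks cells that express Cx3cr1, the fractalkine receptor. There were 11 libraries: 4 from the initial segments (IS), 3 from the caput/corpus and 4 from the cauda, each made from 4 epididymides. The labels do not state which animals each library came from. Per the labels, RNA was taken with a PicoRNA kit, libraries were made with the SMARTer v4 kit, and they were sequenced on a HiSeq2500 instrument. The submitters' processing notes name STAR, HTSeq and edgeR without versions or settings, and the mouse genome build mm9.

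The deposited count files hold whole counts of reads per Ensembl gene for 37583 genes, 1 file per sample, with no normalization. The deposited table of RPKM (reads scaled by gene length and by effective library size) has a column for each of the 11 samples, named by description, region and number. Multiplied by the gene length given in the same table, every RPKM value of a column was a whole multiple of a single step within a tolerance of 0.001, for all 37583 genes in all 11 columns. The whole reads behind each column were recovered in this way. TMM normalization of these reads over all genes gave the effective library size behind the authors' RPKM values in all 11 columns.

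The count files and the RPKM columns disagreed for 3 of the 11 samples. For 8 samples the count file and the column of the same name held the same reads for every gene. The count file under IS replicate 2 equalled no column. The count file under caput/corpus replicate 1 equalled the column named IS replicate 2, and the count file under cauda replicate 1 equalled the column named caput/corpus replicate 1. The column named cauda replicate 1 equalled no count file. All values given here, unless another source is named, are the reads behind the column that carries the sample's name: 10 of these 11 read sets are identical to a deposited count file, and that of cauda replicate 1 was recovered from the RPKM column alone. This choice was made after levels of a few marker genes per library had been seen. The counts as filed, the 8 samples without a conflict, and limma on log2(RPKM + 1) were run as alternatives, also chosen after seeing the data, as was edgeR with robust estimation of the spread.

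Reads recovered per library ranged from 16873180 to 31737132. Counting was not stranded, as the names of the count files state. In the count files as filed, between 12.5% and 35.8% of the reads counted by HTSeq were not uniquely aligned, 7.75% to 24.8% fell on no gene and 1.74% to 2.12% on more than 1 gene. The share not uniquely aligned was 27.6% to 35.8% in the 5 files of the title series Maj3 and 12.5% to 14.7% in the 6 files of Maj4. Reads that align to several paralogs are left out of such counts. Gene symbols were taken from GENCODE M21, which holds 32860 of the 37583 Ensembl identifiers. Genes are given by symbol and Ensembl identifier and not by position, because an annotation of build mm9 was not used here.

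The groups were the 3 regions, and the 3 comparisons between them were each tested once. The titles fall into series Maj3 (5 libraries) and Maj4 (6 libraries), each with all 3 regions, and the series was a covariate. The test was the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) in 1 fit of all 11 libraries, with TMM normalization and filterByExpr by region, which left 15116 genes. A gene was called at an adjusted p (Benjamini-Hochberg over the genes tested, within a comparison) under 0.05. Adjusted p values of genes are from this test unless another is named. Levels are CPM (read counts scaled to the TMM effective library size), as mean ± SD over libraries. Log2 fold changes are from the edgeR fit, ± the standard error derived from its F statistic. Where every library of a group had 0 reads for a gene, the fold is a lower bound against 3 reads over the group, and with 1 to 3 reads it is a ratio of pooled reads with its exact 95% counting interval. Intervals and bounds cover counting error only, since the reads carry no molecular identifiers.

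Before the data were examined, 19 lists of 340 marker and pathway genes were fixed, and all 340 were found in the table. The lists were macrophage identity, conventional dendritic cell, monocyte, perivascular resident-type macrophage, microglia-type homeostatic, MHC class II presentation, inflammatory cytokines and chemokines, regulatory and alternative activation, interferon-stimulated, efferocytosis and complement, pattern recognition receptors, lysosome and lipid handling, immediate early and stress, cell cycle, epididymal epithelium, sperm and germ cell, lymphocyte, neutrophil, and stroma and endothelium. Each was tested against the other genes with limma camera (limma 3.58.1, preset correlation 0.01) on the same fit, adjusted over the 19 lists. The test was repeated with the correlation estimated per list, and with fry, which asks only whether a list's own genes move one way. A list of 23 mast cell and basophil genes was written after the results were seen.

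The named genes were chosen by a rule also fixed before the data were examined. Among called genes with at least 10 CPM in the higher region and a symbol that is not a model number, it took the 8 with the largest log2 fold change and the 5 with the smallest p in each direction. It added up to 4 called members of each list with the smallest p, without a minimum level. It also took the levels of Cx3cr1, Ptprc, Adgre1, Itgam, Itgax, Fcgr1, Csf1r, H2-Ab1, Cd74, Zbtb46 and Ly6c2. The mast cell and basophil genes outside this rule, the genes given for the count file that equals no column, and the genes named because a count was small were chosen after their values were seen. Some genes that the rule takes are not reported here.

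The tests were tried on simulated data, made from the spread of 15116 genes with 100 genes changed 2-fold and 100 changed 4-fold in 1 region. The changed genes were drawn only from those above a minimum mean read count, so recovery of genes with fewer reads was not tried. At 2-fold, edgeR recovered 21% in IS versus caput/corpus, 25% in IS versus cauda and 23% in cauda versus caput/corpus. At 4-fold it recovered 58%, 60% and 56%. It called 3, 5 and 9 unchanged genes. DESeq2 1.42.0 recovered 39%, 38% and 41% at 2-fold and called 56, 80 and 77 unchanged genes. A list of 18 genes changed 2-fold was called by camera in each simulation, with 0, 1 and 0 of the other 18 lists. The simulated genes varied independently and without a title series effect, so camera was not tried on correlated lists. No simulated library was made to stand apart from the others, as cauda replicate 1 does in the real data. In the real data the correlation estimated per list reached 0.752 (perivascular list, IS versus caput/corpus).

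The alternatives fixed before the data were examined were DESeq2 in place of edgeR, RLE in place of TMM size factors, no filter on low counts, no title series in the model, a block by series and number in place of the series, each title series alone, only the libraries of the 2 regions compared, voom with sample quality weights, and leaving out each library in turn. For the lists, the estimated correlation and fry were added. Each comparison was also repeated over the 35 divisions of its libraries into groups of the same sizes.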

Results

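Expression was measured by RNA sequencing in CX3CR1+ mononuclear phagocytes, a family that takes in macrophages, dendritic cells and monocytes, sorted from 3 regions of the mouse epididymis. The epididymis is the duct in which sperm mature, and its regions follow one another from the initial segments (IS) through the caput and corpus to the cauda, where sperm are stored. There were 4 IS, 3 caput/corpus and 4 cauda libraries, each from 4 epididymides. The IS libraries held 28820336, 27034390, 17618698 and 21536359 reads on genes for replicates 1 to 4. The caput/corpus libraries held 28881452, 20635835 and 19591431 reads for replicates 1 to 3. The cauda libraries held 29712956, 31737132, 16873180 and 22544035 reads for replicates 1 to 4. The series title poses the question that all 3 comparisons address, namely how gene expression of these cells differs with their location.

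The count files and the named RPKM columns disagreed on which reads belong to IS replicate 2, caput/corpus replicate 1 and cauda replicate 1. The values below follow the named columns. With these, edgeR called 571 genes between IS and caput/corpus, 2488 between IS and cauda, and 93 between cauda and caput/corpus. With the 8 libraries on which both sources match it called 954, 2409 and 52. With the counts as filed edgeR called 0, 4 and 0 genes, while 1166, 3098 and 992 had an unadjusted p under 0.05, and no other tool was run on them.

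The cells of all 3 regions carried transcripts of the sorted lineage. Cx3cr1 (ENSMUSG00000052336), on whose locus the sort rests, stood at 788 ± 115 CPM in IS (SD, n = 4), 419 ± 117 in caput/corpus (n = 3) and 312 ± 51.7 in cauda (n = 4). Csf1r, the receptor for the macrophage growth factor CSF1, stood at 3273 ± 288, 2224 ± 491 and 1495 ± 416 CPM in the same order. Ptprc, the pan-leukocyte antigen CD45, stood at 666 ± 73.3, 786 ± 109 and 874 ± 85.8 CPM. The macrophage markers Adgre1 and Fcgr1 had means of 830 and 259 CPM in IS, 716 and 214 in caput/corpus, and 509 and 155 in cauda. The integrins Itgam and Itgax were not called in any comparison, with means of 617 and 143 CPM in IS, 496 and 153 in caput/corpus, and 533 and 126 in cauda. Cauda replicate 1 stood apart from the other 10 libraries, with 13434 genes that had a read against 17168 to 17789 in the other cauda libraries. On the first principal component (43.8% of the variance) it lay at 249 while the others lay between -77.8 and 37.1.

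**Figure D1:**
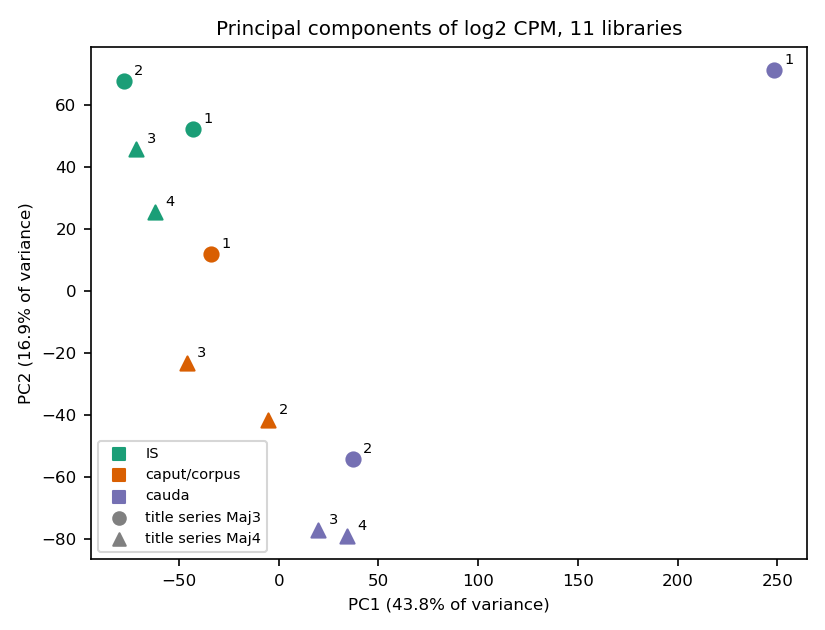
First against second principal component of log2 CPM for the 11 libraries, as percent of variance (43.8% and 16.9%), coloured by region, with replicate numbers beside the points and the title series as the shape. Cauda replicate 1 lies apart on the first axis, and on the second axis the IS libraries lie between 25.6 and 67.8, cauda replicate 1 at 71.3 and the other cauda libraries between -54.0 and -78.9.

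Between IS and caput/corpus, 571 of 15116 genes were called, 120 higher in IS and 451 higher in caput/corpus, and 355 of them differed at least 2-fold. The IS libraries held more Rnase10 (ENSMUSG00000021872), a secreted RNase A family member from the epididymal epithelium list, whose source in the sorted fraction is open. It stood at 230 ± 81.3 CPM in IS (SD, n = 4) and 11.3 ± 5.75 in caput/corpus (n = 3), a log2 fold change of 4.23 ± 0.23 (SE, adjusted p = 6.42e-05). The IS libraries also held more Lilra5, an immunoglobulin-like leukocyte receptor, at 264 ± 46.6 against 95.6 ± 15.1 CPM (log2 1.42 ± 0.14, adjusted p = 0.00151). Cells from caput/corpus carried more Retnla (ENSMUSG00000061100), a product of alternatively activated macrophages, at 1546 ± 39.3 against 45.0 ± 27.4 CPM (log2 -5.08 ± 0.60, adjusted p = 0.00314). St3gal5, the enzyme that makes ganglioside GM3, stood at 111 ± 4.83 CPM in caput/corpus against 39.5 ± 5.11 in IS (log2 -1.54 ± 0.13, adjusted p = 0.00132).

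Dendritic cell and monocyte genes were higher in caput/corpus than in IS. Of the conventional dendritic cell list, 9 of 20 genes were higher in caput/corpus and 0 in IS (10 and 1 adjusted over the list alone), with a camera adjusted p of 4.13e-13 that held with an estimated correlation (adjusted p = 0.0228). Clec10a, a lectin of dendritic cells and macrophages, rose from 129 ± 34.6 to 416 ± 33.5 CPM (log2 -1.74 ± 0.20, adjusted p = 0.00289), Cd209a from 312 to 1043, Irf4 from 29.0 to 84.0 and the cytokine receptor Flt3 from 59.4 to 160 CPM. Zbtb46, a transcription factor of conventional dendritic cells, was called too, at 44.2 ± 8.60 and 83.7 ± 14.3 CPM. Of the monocyte list, 8 of 16 were higher in caput/corpus and 0 in IS (12 and 0 adjusted over the list alone), with an adjusted p of 1.17e-18 (adjusted p = 0.0228 with an estimated correlation). S100a6 stood at 50.9 and 182 CPM, S100a4 at 36.9 and 142 and Ear2 at 21.5 and 109, while Ly6c2 was not called at 12.4 ± 3.40 and 42.2 ± 17.7 CPM. Of the MHC class II presentation list, 7 of 16 were higher in caput/corpus and 1 (Lgmn, a lysosomal protease) in IS (12 and 3 adjusted over the list alone), with an adjusted p of 5.28e-09 that did not hold with an estimated correlation (adjusted p = 0.0622). H2-Ab1 stood at 9467 ± 2148 and 15317 ± 3471 CPM, and Cd74 at 35018 and 50407. Without IS replicate 3, H2-Ab1 and H2-Aa lost their calls (adjusted p = 0.0508 and 0.0523).

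Macrophage and microglia-type genes moved the other way, in few called members. Of the macrophage identity list, Cx3cr1 (log2 0.91 ± 0.20, adjusted p = 0.0369) and the phagocytic receptor kinase Mertk (1.16 ± 0.27, adjusted p = 0.0440) were higher in IS, 2 of 20 (5 higher and 1 lower adjusted over the list alone). By camera, the macrophage identity list had an adjusted p of 2.06e-05, which was lost with an estimated correlation (adjusted p = 0.267) and with fry (0.0764). Of the microglia-type list, the purine receptor P2ry13 (301 ± 43.5 and 133 ± 69.2 CPM) and Tgfbr1 were higher in IS, 2 of 14 (4 and 0 adjusted over the list alone). By camera, the microglia-type list had an adjusted p of 4.62e-06, which was lost with an estimated correlation (adjusted p = 0.267) and with fry (0.0912). Of the efferocytosis and complement list, Msr1 and Mfge8 were higher in IS and Cfp in caput/corpus, 3 of 20 (6 and 1 adjusted over the list alone). By camera, the efferocytosis and complement list had an adjusted p of 0.000391, which was lost with an estimated correlation (adjusted p = 0.267) and with fry (0.105). The calls of these IS genes lay near the threshold, while their folds stayed of similar size with any 1 library left out. Cx3cr1 kept a log2 fold change of 0.77 to 1.20 but was not called without IS replicate 1, 3 or 4, caput/corpus replicate 2 or 3, or cauda replicate 4, with adjusted p up to 0.174. Mertk ranged from 0.96 to 1.35, P2ry13 from 0.97 to 1.61, Tgfbr1 from 0.95 to 1.51 and Mfge8 from 1.43 to 1.89. Mertk, P2ry13, Tgfbr1 and Mfge8 were not called in 7 or 8 of the 11 fits with a library left out. These were among others the fits without IS replicate 1 or 3 or caput/corpus replicate 2 or 3, with adjusted p up to 0.180, 0.180, 0.174 and 0.135, while Msr1 was not called without caput/corpus replicate 3 (adjusted p = 0.0519).

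Among the remaining functional lists, 3 of 21 inflammatory genes (Tnfaip3, Ccl7 and Ptgs2), 2 of 17 regulatory genes (Retnla and Aldh1a2, a retinoic acid synthesis enzyme) and 1 of 18 interferon-stimulated genes (Ifitm3) were higher in caput/corpus, with 0 higher in IS. Adjusted over the list alone, 7, 4 and 4 were higher in caput/corpus and 2, 0 and 0 in IS. Their camera adjusted p values were 0.0176, 0.00266 and 4.95e-05, none of which held with an estimated correlation (adjusted p = 0.267 in each), and the first was also lost without IS replicate 1 (adjusted p = 0.0543), with no title series (0.0589), in the Maj3 libraries alone (0.0572) and with fry (0.0767). The inflammatory list was called in 18 of 25 alternatives, and the regulatory and interferon lists in 23 each. The perivascular list (Stab1 higher in IS, Cd209d and Cd209f in caput/corpus, of 16), pattern recognition receptors (0 of 18), lysosome and lipid handling (Cd9 higher in IS, Lgals3 and Spp1 in caput/corpus, of 16) and cell cycle (0 of 16) were not called, with adjusted p of 0.422, 0.272, 0.705 and 0.466. Adjusted over the list alone, they had 1, 0, 5 and 0 genes higher in IS and 3, 0, 3 and 0 higher in caput/corpus. The perivascular list had a median log2 fold change of 0.04 and a mean of -0.48, and it was called toward caput/corpus without caput/corpus replicate 3 (adjusted p = 0.0126). With 1 library left out, Tnfaip3 and Ccl7 were not called in 5 of the 11 fits (without IS replicate 1, 3 or 4 or caput/corpus replicate 2 or 3), and Ptgs2 in 7, the same fits and those without IS replicate 2 or cauda replicate 3. Their adjusted p reached 0.0874, 0.109 and 0.128. Stab1, Cd9 and Cd209f were not called in 8, 5 and 4 fits, with adjusted p up to 0.214, 0.0819 and 0.0902, and all 3 kept their direction.

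Genes of other cell types and of cell stress moved with the same regions. Of the epididymal epithelium list, 7 of 24 were higher in IS (Rnase10, Lcn8, Lcn9, Gpx5, Adam28, Cst8 and Ovch2) and Lcn5 was higher in caput/corpus, at 66.6 ± 29.9 against 1.32 ± 0.500 CPM (log2 -5.70 ± 0.50, adjusted p = 0.00132). Adjusted over the list alone 8 and 2 were called, and the camera adjusted p of 1.42e-06 did not hold with an estimated correlation (adjusted p = 0.250). The largest folds included Adam28, Teddm2, Actg2 (a smooth muscle actin), Defb48, Cst12 and Ly6g5b in IS and Spink11 in caput/corpus. Adam28 was not called without IS replicate 1, 2 or 3 or caput/corpus replicate 3 (adjusted p up to 0.0812), and its log2 fold change ranged from 5.13 to 6.81 with a library left out. Wfdc13 and Serpina1f had 1 read over the 4 IS libraries, with read ratios of 1542 (95% interval 276 to 60974) and 1040 (186 to 41131). Wfdc13 was not called without IS replicate 2 or 3 (adjusted p up to 0.0659; log2 -11.73 to -9.92), and Serpina1f not without IS replicate 1 or 3 or caput/corpus replicate 1 (up to 0.0848; log2 -10.86 to -8.69). Mast cell genes were among the largest folds to caput/corpus, as with Hdc, the histamine-forming enzyme, at 0.905 ± 0.771 and 30.5 ± 24.4 CPM, Mrgprb1 and the IgE receptor gene Fcer1a. Of the immediate early and stress list, 17 of 20 were lower in IS and 0 higher (19 and 0 adjusted over the list alone), as with Fosb at 23.3 ± 8.84 and 116 ± 40.5 CPM. By camera, the immediate early and stress list had an adjusted p of 1.48e-36, which held with an estimated correlation (adjusted p = 0.0228). The lymphocyte, sperm and germ cell, neutrophil, and stroma and endothelium lists had 0 of 17, 6, 3 and 17 genes called, and none of these lists was called. Their adjusted p were 0.0777, 0.779 and 0.705 for lymphocyte, sperm and stroma genes, and adjusted over the list alone 1 neutrophil gene was higher in each region and 0 genes of the others. The sperm list had a median log2 of 0.17 and a mean of -0.64. The lymphocyte list was called in 13 of 25 alternatives, and leaned toward caput/corpus in all 25. These were the fits without IS replicate 2 (0.0147) or 4 (0.0214), caput/corpus replicate 2 (0.0155) or cauda replicate 1 (0.0131), with no filter (0.0265) or no title series (0.0156), in the Maj4 (0.0374) or Maj3 libraries alone (0.0165) and with only the libraries of both regions (0.0150). It was also called with voom (0.000955), in the 8 libraries on which both sources match (0.0198), with limma on RPKM (0.00913) and with the counts as filed (0.00391), but not with an estimated correlation (adjusted p = 0.693) or fry (0.403). The sperm list was called in the Maj3 libraries alone (0.000325).

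As limits, edgeR called 457 genes in the 6 Maj4 libraries alone and 0 in the 5 Maj3 libraries alone. The latter hold a lone caput/corpus library assumed to vary like the other groups (404 at an unadjusted p under 0.05). With no title series in the model it called 233. Leaving out IS replicate 1, 3 or 4, or caput/corpus replicate 2 or 3, gave 280, 244, 374, 234 and 269 genes, and leaving out cauda replicate 1 gave 1353. DESeq2 and voom with quality weights called 1343 and 1707, with 38.0% and 37.3% of them higher in IS against 120 of 571 with edgeR. With the counts as filed, the epithelial and inflammatory lists turned direction without a call (adjusted p = 0.149 and 0.351), and the immediate early list was not called (0.340).

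**Figure D2:**
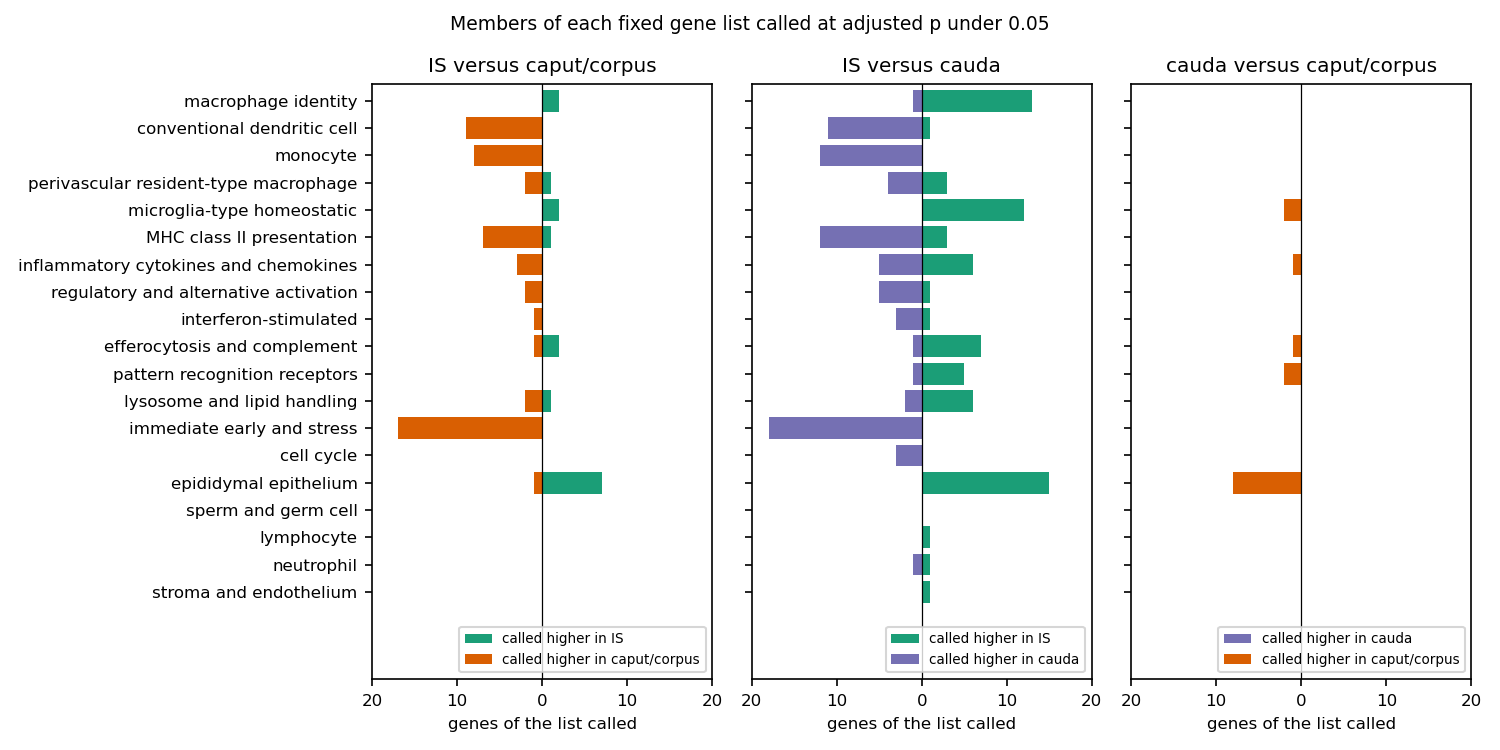
Members of each of the 19 fixed gene lists called at adjusted p under 0.05 in each comparison, as numbers of genes from 0, with the bar's side and colour giving the region in which they were higher. In IS versus cauda, 13 macrophage and 12 microglia-type genes were higher in IS, and 11 dendritic cell and 12 monocyte genes were higher in cauda.

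Between IS and cauda, the ends of the duct, 2488 of 15116 genes were called, 1119 higher in IS and 1369 higher in cauda, and 1419 of them differed at least 2-fold. Cells from IS carried more Apoe (ENSMUSG00000002985), the lipid carrier made by many macrophages, at 51355 ± 10545 CPM (SD, n = 4) against 11590.0 ± 2171 in cauda (n = 4; log2 2.13 ± 0.24, adjusted p = 0.000355). P2ry13 (ENSMUSG00000036362) stood at 301 ± 43.5 against 44.0 ± 10.6 CPM (log2 2.75 ± 0.26, adjusted p = 0.000149), and the lysosomal protease Ctsd at 4157 ± 964 against 614 ± 84.0 (log2 2.72 ± 0.29, adjusted p = 0.000256). Cells from cauda carried more Retnla, at 4036 ± 1902 against 45.0 ± 27.4 CPM (log2 -6.52 ± 0.63, adjusted p = 0.000162), and more Crip1, at 1168 ± 156 against 242 ± 28.3 (log2 -2.27 ± 0.13, adjusted p = 9.67e-06). The genes with the smallest p toward cauda also included St3gal5, Lgals1 (galectin-1), Fgfr1 and Ryr1.

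Macrophage and microglia-type genes were higher in IS in most of their tested members. Of the macrophage identity list, 13 of 20 were higher in IS and 1 in cauda (16 and 1 adjusted over the list alone), as with Mertk (156 ± 57.0 and 39.6 ± 20.2 CPM) and Cx3cr1 (log2 1.34 ± 0.19, adjusted p = 0.00101). By camera, the macrophage identity list had an adjusted p of 1.97e-09, which was lost with an estimated correlation (adjusted p = 0.110). Csf1r, Adgre1 and Fcgr1 were among the macrophage genes higher in IS (log2 1.14 ± 0.21, 0.66 ± 0.16 and 0.72 ± 0.13), and Ptprc was higher in cauda (log2 -0.40 ± 0.12, adjusted p = 0.0493). Of the microglia-type list, 12 of 14 were higher in IS and 0 in cauda (13 and 0 adjusted over the list alone), as with Tgfbr1 (626 ± 216 and 169 ± 84.9 CPM) and Fcrls (476 ± 119 and 125 ± 41.9 CPM). Sall1, a transcription factor of microglia, had 2 reads over the cauda libraries and a read ratio of 1120 (95% interval 310 to 9254). By camera, the microglia-type list had an adjusted p of 6.12e-13, which was lost with an estimated correlation (adjusted p = 0.0935). Of the efferocytosis and complement list, 7 of 20 were higher in IS and 1 (Cfp) in cauda (10 and 1 adjusted over the list alone), as with the integrin Itgb5 (607 ± 74.0 and 112 ± 26.6 CPM) and the scavenger receptor Msr1 (263 ± 71.3 and 69.1 ± 14.2 CPM). By camera, the efferocytosis and complement list had an adjusted p of 7.13e-05, which was lost with an estimated correlation (adjusted p = 0.208). The macrophage identity, microglia-type and efferocytosis lists were each called in 24 of 25 alternatives, which kept the preset correlation apart from the estimated correlation and fry. With fry their adjusted p were 0.000971, 0.000714 and 0.00494. These lists moved together with the epithelial list, which was also higher in IS.

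Dendritic cell, monocyte and antigen presentation genes were higher in cauda. Of the conventional dendritic cell list, 11 of 20 were higher in cauda and 1 in IS (11 and 1 adjusted over the list alone), as with Clec10a (129 ± 34.6 and 571 ± 125 CPM), Irf4, Cd209a, Flt3 and Zbtb46 (44.2 ± 8.60 and 106 ± 14.8 CPM). By camera, the conventional dendritic cell list had an adjusted p of 1.97e-09, which held with an estimated correlation (adjusted p = 0.0337). Of the monocyte list, 12 of 16 were higher in cauda and 0 in IS (12 and 0 adjusted over the list alone), as with S100a4 (36.9 ± 13.7 and 240 ± 28.5 CPM), S100a6, Fn1 and Ly6c2 (log2 -2.60 ± 0.59, adjusted p = 0.0137), whose cauda mean of 77.6 ± 73.8 CPM includes 188 in cauda replicate 1. By camera, the monocyte list had an adjusted p of 3.71e-12, which was lost with an estimated correlation (adjusted p = 0.0566). Of the MHC class II list, 12 of 16 were higher in cauda and 3 in IS (12 and 4 adjusted over the list alone). By camera, the MHC class II list had an adjusted p of 1.51e-06, which was lost with an estimated correlation (adjusted p = 0.0935). The class II chains H2-Ab1 (log2 -0.91 ± 0.13) and H2-Aa (log2 -0.88 ± 0.11) and their chaperone Cd74 (log2 -0.75 ± 0.13) were higher in cauda, while Cd86, a costimulatory ligand, was higher in IS (279 ± 71.6 and 103 ± 22.4 CPM). Beside these lists, 18 of 20 immediate early and stress genes were higher in cauda and 0 in IS (19 and 1 adjusted over the list alone), as with Fosb (130 ± 36.8 CPM in cauda) and Klf2. By camera, the immediate early and stress list had an adjusted p of 1.36e-14, which was lost with an estimated correlation (adjusted p = 0.0935). The monocyte and MHC class II lists were each called in 24 of 25 alternatives and the immediate early list in 23. With fry their adjusted p were 0.00049, 0.000701 and 0.00138.

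Cytokine and sensing genes went both ways. Of the inflammatory list, 6 of 21 were higher in IS, as with the chemokines Cxcl16 and Cxcl10 and the adhesion receptor Icam1, and 5 in cauda, as with Tnfaip3 (6 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.993). Of the regulatory list, 5 of 17 were higher in cauda, among them Retnla and Aldh1a2, and 1 (Il4ra) in IS (5 and 1 adjusted over the list alone), without a list call (adjusted p = 0.152). It was called toward cauda in 4 of 25 alternatives: without cauda replicate 1 (0.0495), in the 8 libraries on which both sources match (0.0115), in the Maj4 libraries alone (0.0157) and with no title series (0.0463). Of the interferon-stimulated list, 3 of 18 (Ifitm3, Mx1 and Zbp1) were higher in cauda and 1 (Bst2) in IS (8 and 1 adjusted over the list alone). Its list call was lost without cauda replicate 1 (0.0569) or 3 (0.0601) or IS replicate 3 (0.0680) or 4 (0.0938). By camera, the interferon-stimulated list had an adjusted p of 0.0293, which was lost with an estimated correlation (adjusted p = 0.466). Of the pattern recognition list, 5 of 18 were higher in IS, among them Nod1 and Clec4n (Dectin-2), and 1 in cauda (5 and 1 adjusted over the list alone; adjusted p = 0.0597). This list was called toward IS in 11 of 25 alternatives: without cauda replicate 1 (0.0125) or caput/corpus replicate 2 (0.0468) or 3 (0.0343), with RLE (0.0445) or no filter (0.0364), in the Maj4 libraries alone (0.0413), with only the libraries of both regions (0.0434), with voom (0.0288), in the 8 libraries (0.0246), with the counts as filed (0.0375) and with fry (0.000714). It was not called with an estimated correlation (adjusted p = 0.179). The interferon list was called in 16 of 25 alternatives, and not in the Maj3 libraries alone (0.424), with voom (0.0928), in the 8 libraries (0.0699) or with the counts as filed (0.291). The perivascular list was called toward cauda in the Maj4 libraries alone (0.0350) and with the counts as filed (0.00684). Of the lysosome list, 6 of 16 were higher in IS, as with Ctsd and Ctsl, and 2 in cauda, as with Lgals3 (247 ± 41.0 and 962 ± 246 CPM). Of the lysosome genes 7 and 5 were called adjusted over the list alone, without a list call (adjusted p = 0.181). Of the perivascular list, 3 of 16 were higher in IS (Stab1, Igf1 and Maf) and 4 in cauda, as with the hemoglobin scavenger receptor Cd163 (4 and 5 adjusted over the list alone; adjusted p = 0.854). The medians of the perivascular, inflammatory and regulatory lists (log2 0.27, -0.26 and 0.02) differed in sign from their means (-0.39, 0.19 and -0.52). Of the cell cycle list, Aurkb, Ccnb2 and Mcm6 were higher in cauda, 3 of 16 (5 and 0 adjusted over the list alone). Ccnb2 was not called without IS replicate 1, 2 or 4 (adjusted p up to 0.0753), and Mcm6 without any 1 of the IS libraries or of cauda replicates 2 to 4 (up to 0.0931). Zbp1 and Il4ra were not called in 4 and 2 of the 11 fits with a library left out (up to 0.0822 and 0.0640). By camera, the cell cycle list had an adjusted p of 0.00505, which was lost with an estimated correlation (adjusted p = 0.0935). It was called in 24 of 25 alternatives, fry among them (adjusted p = 0.000701).

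Epithelial transcripts were among the largest folds toward IS. Of the epididymal epithelium list, 15 of 24 were higher in IS and 0 in cauda (19 and 0 adjusted over the list alone). By camera, the epididymal epithelium list had an adjusted p of 1.86e-29, which held with an estimated correlation (adjusted p = 0.0337). Gpx5 (ENSMUSG00000004344), the secreted epididymal glutathione peroxidase, stood at 796 ± 293 CPM in IS and 0.623 ± 0.286 in cauda (log2 10.33 ± 0.35, adjusted p = 2.20e-07), and Lcn8 and Lcn9, epididymal lipocalins, at 267 ± 77.2 and 347 ± 125 in IS and 0.0871 and 0.129 in cauda. Cst8, Ovch2 and Cst11 had 1, 1 and 3 reads over the cauda libraries, with read ratios of 9284 (95% interval 1666 to 366720), 3664 (657 to 144761) and 4351 (1488 to 21101). Cldn2, Defb47 and Krt23 had 0 reads in cauda and were at least 549-fold, 447-fold and 506-fold higher in IS. Toward cauda, the largest folds included genes of mast cells and basophils, as with Prss34, a basophil protease, at 49.1 ± 38.5 against 0.245 ± 0.290 CPM (log2 -7.76 ± 0.72, adjusted p = 0.000132), Mrgprb1, Mrgprb2, Tph1, Cyp11a1 and Hdc. Of other cell types, 1 of 17 lymphocyte genes (Klrb1c, in IS), 1 of 17 stroma genes (Pdgfra, in IS), Csf3r in IS and Mmp8 in cauda of 3 neutrophil genes (median and mean log2 -1.68 and -1.18, with the camera direction toward IS), and 0 of 6 sperm genes were called. The adjusted p of these lists were 0.420, 0.0319 (adjusted p = 0.561 with an estimated correlation), 0.763 and 0.758, in that order of lists, with 0, 1, 1 and 0 genes higher in IS and 1 neutrophil gene higher in cauda adjusted over the list alone, and the stroma call was lost without IS replicate 2 (0.159) or 3 (0.0583) or cauda replicate 1 (0.0628). The stroma list was called in 15 of 25 alternatives, and not in the 8 libraries (0.309), the Maj3 libraries alone (0.0524), with only the libraries of both regions (0.0677), with voom (0.102), with fry (0.0878) or with the counts as filed (0.498). Klrb1c was not called in 8 and Mmp8 in 4 of the 11 fits with a library left out (adjusted p up to 0.0894 and 0.0949).

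As limits, edgeR called 1144 genes in the Maj4 libraries alone, 30 in the Maj3 libraries alone and 1481 with no title series in the model. Leaving out IS replicate 3 gave 1641 genes, leaving out cauda replicate 1 gave 3124, and DESeq2 and voom with quality weights called 3806 and 4399. Which region had more of the called genes turned with the choice: more were higher in IS with RLE (1230 against 1189 in cauda), DESeq2 (2063 and 1743), no title series (754 and 727), the Maj4 (589 and 555) or Maj3 libraries alone (18 and 12), only the libraries of both regions (985 and 980) and limma on RPKM (1546 and 1522). The immediate early list was not called with the counts as filed (adjusted p = 0.606).

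**Figure D3:**
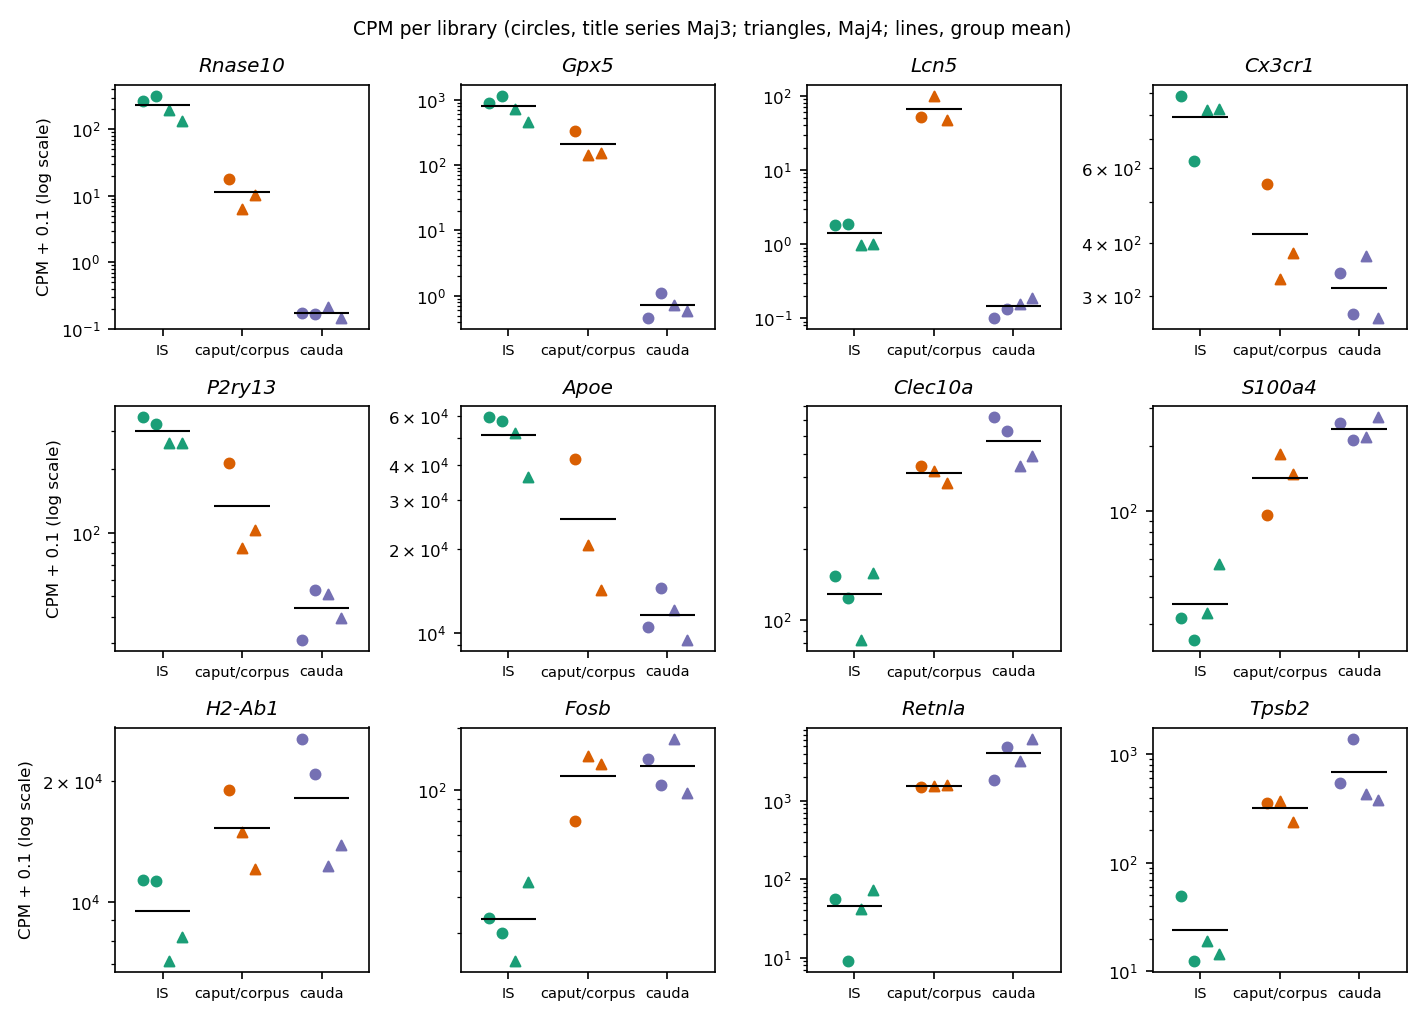
CPM + 0.1 on a log axis for 12 named or marker genes in the 11 libraries, by region, with circles for title series Maj3, triangles for Maj4 and lines for the group means. Cx3cr1, P2ry13 and Apoe have their highest means in IS (788, 301 and 51355 CPM), Retnla and Tpsb2 have their lowest there (45.0 and 23.8 CPM), and the epithelial genes Rnase10, Gpx5 and Lcn5 are near 0 in cauda.

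Between cauda and caput/corpus, 93 of 15116 genes were called, 5 higher in cauda and 88 higher in caput/corpus, and 80 of them differed at least 2-fold. The 5 higher in cauda were Cotl1 (ENSMUSG00000031827) and Coro1c, both of which bind actin, St3gal5, Lgals1 and Snx9, which acts in endocytosis, and all 5 fall under the rule for named genes. Cotl1 stood at 1051 ± 353 CPM in cauda (SD, n = 4) and 515 ± 235 in caput/corpus (n = 3; log2 0.91 ± 0.13, adjusted p = 0.0120), and Coro1c at 237 ± 5.75 and 153 ± 14.5 CPM (log2 0.65 ± 0.11, adjusted p = 0.0304). St3gal5, Lgals1 and Snx9 had log2 fold changes of 0.70, 0.57 and 0.56, and adjusted p of 0.0420, 0.0386 and 0.0398. All 5 lost their call without caput/corpus replicate 1, with adjusted p between 0.0822 for Cotl1 and 0.299 for St3gal5. Cotl1 was also lost without caput/corpus replicate 3 (0.0573), and the others in 9 or 10 of the 11 fits with a library left out. Over 24 alternatives the log2 fold change of Cotl1 ranged from 0.68 to 1.03 and those of the others from 0.46 to 0.91, all higher in cauda. None of the 5 was called with no title series, in either title series alone or with only the libraries of both regions in the fit. In caput/corpus, Nod1, a sensor of bacterial peptidoglycan, was higher at 49.5 ± 4.15 against 25.7 ± 2.15 CPM (log2 -0.91 ± 0.12, adjusted p = 0.00842). Its adjusted p was 0.0918 without caput/corpus replicate 1.

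Genes of the epididymal epithelium were among the largest folds. Of that list, 8 of 24 were higher in caput/corpus and 0 in cauda (19 and 0 adjusted over the list alone). By camera, the epithelial list had an adjusted p of 1.15e-58, which held with an estimated correlation (adjusted p = 0.00650). Gpx5 stood at 207 ± 103 CPM in caput/corpus and 0.623 ± 0.286 in cauda (log2 -8.48 ± 0.33, adjusted p = 2.19e-06), Rnase10 at 11.3 and 0.0746, and Lcn5 at 66.6 and 0.0449. The beta-defensins Defb20 and Defb30, Cst11, C4bp and Spink11 were also among the largest folds. Epp13 and Defb47 had 0 reads in cauda and were at least 627-fold and 386-fold higher in caput/corpus. Defb47 was not called without IS replicate 4 (adjusted p = 0.0519), and Spink11 not without caput/corpus replicate 1 (adjusted p = 0.0501).

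Of the macrophage-related lists, few members passed on their own. Of the microglia-type list, Sall1 and P2ry13 (133 ± 69.2 and 44.0 ± 10.6 CPM) were higher in caput/corpus, 2 of 14 (11 and 0 adjusted over the list alone). By camera, the microglia-type list had an adjusted p of 1.04e-12, which was lost with an estimated correlation (adjusted p = 0.222). The macrophage identity list had 0 of 20 genes called (5 higher in caput/corpus adjusted over the list alone). By camera, the macrophage identity list had an adjusted p of 3.68e-06, which was lost with an estimated correlation (adjusted p = 0.329). Toward caput/corpus, efferocytosis and complement had Msr1 of 20 (2 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.519 with an estimated correlation). Inflammatory genes had Icam1 of 21 (2 adjusted over the list alone; adjusted p = 0.00720, and adjusted p = 0.329 with an estimated correlation). Lysosome and lipid handling had 0 of 16 (5 adjusted over the list alone; adjusted p = 0.00712, and adjusted p = 0.237 with an estimated correlation), also toward caput/corpus. The cell cycle list was higher in cauda with 0 of 16 genes called (1 adjusted over the list alone; adjusted p = 0.000525, and adjusted p = 0.0812 with an estimated correlation). The lymphocyte and stroma lists were higher in caput/corpus with 0 of 17 genes called in each (0 and 1 adjusted over the list alone; adjusted p = 0.000711 and 0.00285, and adjusted p = 0.519 in both with an estimated correlation). The lists not called were pattern recognition (Nod1 and Clec4n of 18 higher in caput/corpus, 0.112), dendritic cell (0 of 20, 0.119), monocyte (0 of 16, 0.112), perivascular (0 of 16, 0.223), MHC class II (0 of 16, 0.262), regulatory (0 of 17, 0.530), interferon (0 of 18, 0.396), immediate early and stress (0 of 20, 0.150), sperm (0 of 6, 0.396) and neutrophil genes (0 of 3, 0.395), with their adjusted p in brackets. Adjusted over the list alone, these had 2, 0, 4, 2, 1, 0, 0, 0, 1 and 1 genes, of which 3 monocyte genes were higher in cauda. With 1 library left out, some of these lists were called. Toward cauda these were monocyte genes without IS replicate 3 (0.0357), caput/corpus replicate 2 (0.0205) or cauda replicate 3 (0.0120), dendritic cell genes without cauda replicate 3 (0.0316) and MHC class II genes without caput/corpus replicate 2 (0.0353). Toward caput/corpus, immediate early genes were called without caput/corpus replicate 1 (0.000678) or cauda replicate 1 (0.0174) or 3 (0.0129). Perivascular genes were called without caput/corpus replicate 3 (0.0172) or cauda replicate 3 (0.0129), and pattern recognition genes without cauda replicate 1 (0.0267) or caput/corpus replicate 3 (0.0190). Over 25 alternatives, immediate early genes were called in 6, monocyte genes in 5, dendritic cell and pattern recognition genes in 4 each, perivascular genes in 3, MHC class II and sperm genes in 2 each and neutrophil genes in 1. Of the lists called, efferocytosis was called in 16, inflammatory genes in 19, macrophage identity, lysosome and stroma in 22 each and lymphocyte in 23. With fry, the macrophage identity (adjusted p = 0.0507), inflammatory (0.0529), efferocytosis (0.186), lymphocyte (0.164) and stroma (0.180) calls were lost. The microglia-type (0.0256), lysosome (0.0242), cell cycle (0.0211) and epithelial (0.000753) calls held with fry. It also called pattern recognition (0.0242) and neutrophil genes (0.0249) toward caput/corpus. Sall1 was not called without cauda replicate 2, 3 or 4 (adjusted p up to 0.0723), and its log2 fold change ranged from -9.60 to -5.83. P2ry13, Icam1, Msr1 and Clec4n were lost in 8 or 9 of the 11 fits with a library left out, with adjusted p up to 0.177, 0.308, 0.279 and 0.226. Fits that lost all 4 were those without IS replicate 1, 2 or 4, caput/corpus replicate 1 or cauda replicate 2 or 4. The efferocytosis call was lost without caput/corpus replicate 1 (0.173) or 3 (0.0728) or cauda replicate 1 (0.0596), and the inflammatory call without caput/corpus replicate 3 (0.0668) or cauda replicate 4 (0.105).

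As limits, 1772 genes had an unadjusted p under 0.05, and edgeR called 28 genes in the Maj4 libraries alone and 5 in the Maj3 libraries alone. It called 8 with only the libraries of both regions in the fit, and 0 genes in these 3 fits were higher in cauda (1289, 749 and 1032 genes had an unadjusted p under 0.05 in either direction). Without a filter it called 184, of which 11 were higher in cauda. DESeq2 called 684 genes, 130 higher in cauda and 554 in caput/corpus, and voom with quality weights called 668, 225 and 443. Leaving out IS replicate 1, 3 or 4, caput/corpus replicate 1 or 3, or cauda replicate 4 gave 58, 58, 55, 29, 58 and 49 genes, and leaving out cauda replicate 1 gave 205.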

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

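The tests of the patterns on sample names, epithelial genes and mast cell genes were all chosen after the results were seen, while the divisions of the libraries were planned before the data were examined.

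Over 81 measures, each taken in the 4 IS and the 4 cauda libraries (162 sets), 15 sets held a library far from the other 3 by Dixon's gap test. The test's rate of about 1 in 20 is no guide to chance here. Some of the genes were chosen after their values were seen, and a gene at 0 in the other 3 libraries passes with any read. Cauda replicate 1 held 3 of these values: 13434 genes with a read (others 17168 to 17789), 188 CPM of the monocyte gene Ly6c2 (33.9 to 49.5) and 0.0355 CPM of Cst8 (0 in the others). Cauda replicate 2 held the highest values of the mast cell genes Tpsb2 (1399 CPM, others 382 to 551), Cma1 (1102, others 263 to 352), Cpa3 (913, others 213 to 279.9), Mcpt4 (406, others 102 to 153) and Fcer1a (97.4, others 28.3 to 33.7), and of the scavenger receptor Msr1 (90.2, others 60.1 to 64.6). Coro1c stood at 169 CPM in IS replicate 4 (135 to 139). The rest were genes near 0 in the group: Ovch2 at 0.0439 CPM (others 0) and Adam28 at 0.439 (0 to 0.0677) in cauda replicate 4, Sall1 at 0.116 (0) in cauda replicate 3, Wfdc13 at 0.0376 (0) in IS replicate 2 and Serpina1f at 0.0354 (0) in IS replicate 1. Outside the comparisons, the count file under IS replicate 2 holds 30383072 reads that no RPKM column holds.

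For 3 of the 11 samples the count file held other reads than the RPKM column of that name. Over 2499 genes called in the 8 samples without a conflict, all 3 columns lay nearest the region of their name. The columns named IS replicate 2 and cauda replicate 1 correlated with their regions at 0.797 and 0.573. That of caput/corpus replicate 1 did so at only 0.294 (0.0965 with IS). This argues against the columns carrying names from another region, while a swap of names within a region would not be seen. Of the 3 count files, 0 lay nearest the region they are filed under, as would be seen if the count files are filed under other samples. The files under caput/corpus replicate 1 and cauda replicate 1 hold the reads of columns already placed, so for them this repeats the test of the columns. TMM on the counts as filed gave 0 of the authors' 11 effective library sizes, which argues against the authors having scaled the libraries as filed. Since TMM on the named columns gave all 11, this was to be foreseen and adds no separate evidence on which names are right. The count file that equals no column correlated at 0.184 with caput/corpus, 0.066 with cauda and -0.157 with IS, and no sample is titled Maj3-3 or coded 2MAB, while Maj3 has a caput/corpus 2 and no caput/corpus 1; no label ties the file to that gap, so its sample stays open, and no biological explanation was tested.

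Epididymal epithelium genes were higher in IS than in cauda in sorted phagocytes. In the 8 libraries without a conflict 15 of these genes were called higher in IS, which argues against wrong labels as the cause. If whole epithelial cells of 1 makeup had been sorted along, broad epithelial genes (Epcam, Krt8, Krt18, Cdh1 and Cldn4) would keep a fixed ratio to secretory ones (Rnase10, Gpx5, Lcn8, Lcn9, Cst8, Ovch2 and Adam28) across the IS libraries; the ratio varied 3.34-fold, but 1.85-fold without IS replicate 2, and the limit was set after a first look. Whole cells, RNA released from epithelial cells and material taken up by the phagocytes therefore cannot be told apart. A difference between the regions' own cells was not tested.

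Of 21 tested genes of the mast cell and basophil list, 15 were higher in caput/corpus and 20 in cauda than in IS, 1 (Hpgds) was higher in IS in both, and edgeR, the only tool run on this list, called 0 between cauda and caput/corpus, where 5 had an unadjusted p under 0.05. With any 1 library left out at least 15 were higher in cauda (15 without cauda replicate 2), which argues against 1 library setting the difference, while 9 to 20 were higher in caput/corpus, with 9 without caput/corpus replicate 1. Once region and series means were removed, the genes varied together with a mean correlation of 0.303, above all 1000 random lists (highest 0.294). Without cauda replicate 2 it was 0.209, at percentile 98.3 (highest random list 0.404). The random lists were matched on level alone, so genes of any shared program could exceed them. The correlation therefore cannot tell cells of another type in the sorted fraction, which remain a possible source, from expression by the phagocytes. Tpsb2, Cma1 and Cpa3 stood at 692, 503 and 414 CPM in cauda and 23.8, 17.3 and 11.0 in IS, 0 of the 23 genes are in another list, and the sort on EGFP is a gate that would remove cells without Cx3cr1 expression. Expression by the sorted phagocytes themselves stays open and was not tested.

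The numbers of genes called exceeded those of other divisions of the libraries. For IS versus caput/corpus, 1 of the 35 divisions, the real one, called as many genes (571, highest other 0). For IS versus cauda it was 1 of 35 (2488, highest other 0) and for cauda versus caput/corpus 1 of 35 (93, highest other 1). Every other division mixes libraries of both regions in a group, which widens the spread within groups where the regions differ. The divisions therefore do not show what chance alone would give, and 1 of 35 is the smallest share they allow. For the lists, 5 of 35 divisions called as many as the 11 of IS versus caput/corpus (highest other 11). In IS versus cauda 6 of 35 called as many as the 11 (highest other 12). In cauda versus caput/corpus 5 of 35 called as many as the 9 (highest other 13). Some of these divisions keep most libraries of a region together, as with IS replicates 1, 2 and 4 and cauda replicate 3 (12 lists). The list counts of the divisions therefore cannot decide whether chance gave the list calls, and chance is not excluded.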

How the results depend on the processing

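The counts as filed, the 8 libraries without a conflict, limma on log2(RPKM + 1) and robust estimation were chosen after seeing the data, the other alternatives before. Main counts were 571, 2488 and 93 genes for IS versus caput/corpus, IS versus cauda and cauda versus caput/corpus, and 11, 11 and 9 lists. In that order, DESeq2 called 1343, 3806 and 684 genes, with 38.0%, 54.2% and 19.0% higher in the first region, and voom with quality weights 1707, 4399 and 668, with 37.3%, 47.4% and 33.7%. No filter gave 184 for cauda versus caput/corpus, and no title series gave 233 and 1481 for the comparisons with IS. Maj4 alone gave 1144 for IS versus cauda and 28 for cauda versus caput/corpus, and Maj3 alone, with 5 libraries, gave 0 (404 unadjusted), 30 and 5. Fitting only the libraries compared gave 914 for IS versus caput/corpus and 8 for cauda versus caput/corpus. The counts as filed gave 0, 4 and 0 genes (1166, 3098 and 992 unadjusted), the 8 libraries 954 and 52 and limma on RPKM 934 and 143 for the comparisons with caput/corpus. Leaving out 1 library gave 234 to 1353, 1641 to 3124 and 29 to 205 genes, and 10 to 12, 9 to 12 and 8 to 13 lists. An estimated correlation left 3, 2 and 1 lists called, and fry called 7 for IS versus caput/corpus. Some fits held fewer libraries, and the cause of these differences was not tested.

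Of 58, 83 and 22 named gene results, 41, 73 and 9 kept their call with each library left out. In every alternative, the counts as filed among them, 0, 0 and 0 kept it. Over 1392, 1992 and 528 values under the alternatives, 1160, 1750 and 341 kept direction and call, 228, 238 and 187 kept direction without the call, and 4, 4 and 0 reversed. All reversals were with the counts as filed. In IS versus caput/corpus these were Tnfaip3 (log2 0.17), Klf2 (0.12), Dusp1 (0.0102) and Ier2 (0.23), and in IS versus cauda Tnfaip3 (0.36), Vegfa (0.21), Ier2 (0.14) and Dusp1 (0.0421). The counts as filed place the file that equals no column in IS, and Dusp1 stood at 9480 CPM in it (397 to 2722 in the 11 libraries). Of the reversed genes only Dusp1 was looked up in that file, and the cause was not tested.

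A block by series and number gave 41 genes for cauda versus caput/corpus, 0 of them higher in cauda, so it ended the calls of the 5 genes higher in cauda. With it, the inflammatory list was not called for IS versus caput/corpus (adjusted p = 0.0896), the dendritic cell list was called for cauda versus caput/corpus (0.0462), and no other list call changed. The number is that of the source name within a series, not the replicate number used here, so that IS replicate 2 and caput/corpus replicate 1 share it. In deviations from region means, 9 of 10 pairs of libraries with the same number correlated over 0.1 (-0.014 to 0.394), and 6 of 11 libraries correlated best with their own number. These values also hold what a title series shares. Once series means were removed as well, which by itself lowers correlations within a series, 2 of 10 pairs were over 0.1 (-0.242 to 0.284) and 1 of 11 libraries correlated best with its own number. Since on neither measure every pair was over 0.1, and the labels name no shared animal, the numbers were not taken to pair libraries.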

Other observations

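The count file under IS replicate 2 that equals no RPKM column entered only the alternative that used the counts as filed. Some genes of the immediate early and stress list stood far higher in it than in the 11 libraries. These were among others Fos at 11171 CPM (818 to 5356 in the 11), Jun at 10709.8 (866 to 2524), Atf3 at 8237 (97.0 to 1422) and the chaperone gene Dnajb1 at 3288 (47.9 to 294). The list as a whole was not examined in this file. The chemokine genes Ccl4 and Ccl3 stood at 6702 CPM (191 to 1075) and 3974 (296 to 928), the cytokine gene Tnf at 834 (55.2 to 123) and the heme-degrading enzyme Hmox1 at 753 (73.6 to 126). Its Cx3cr1 was 450.0 CPM, its Retnla 331 and its Tpsb2 201, and Spink8 stood at 87.9 CPM (2.68 to 69.3 in the 11). Its Gpx5 of 229.8 CPM, Lcn8 of 13.7 and Rnase10 of 13.4 lay within the caput/corpus range (144 to 326, 1.70 to 31.3 and 6.31 to 17.6), below the IS range (446 to 1146, 169 to 358 and 136 to 322) and above the cauda range (0.355 to 1.02, 0 to 0.176 and 0.0439 to 0.116). Its Lcn5 of 18.8 CPM lay between the IS range (0.863 to 1.77) and the caput/corpus range (46.6 to 101), as did its Retnla (8.90 to 73.9 in IS and 1502 to 1578 in caput/corpus). These genes were chosen after their values were seen.

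Members of the same list went different ways along the duct. Among class II presentation genes, H2-Ab1 stood at 9467 CPM in IS and 18151 in cauda, while Lgmn stood at 1691 and 847. In the perivascular list, Stab1 stood at 1396 CPM in IS and 342 in cauda and Maf at 238 and 134, while Cd163 stood at 83.0 and 219. The microglia-type gene Sall1 stood at 25.3 ± 20.8 CPM in IS, with 7.75 and 6.99 in the Maj3 libraries and 42.7 and 43.9 in the Maj4 libraries, a difference that was not tested. The title series itself was associated with 3073 genes at an edgeR adjusted p under 0.05.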
